A study of Mus musculus with 5 samples.

How the data were processed

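Gene expression was measured in whole lung of female mice with 1 array for each of 5 strains. The strains were C57BL/6J, called C57, and 4 backcrossed lines named by the labels as 4B(+/+), 4B(-/-), 4D(+/+) and 4D(-/-), which are wild type or knockout for PDE4B or PDE4D. PDE4B and PDE4D are phosphodiesterases that break down cyclic AMP. Per the labels' protocols, the lines had 11 or more generations of backcrossing to C57, and the animals were naive, without the elastase that produces emphysema in the model named by the series title. Per the same protocols, 5 lungs per strain were frozen and powdered, the RNA was checked on a Bioanalyzer, and RNA of 3 of the 5 lungs was mixed for each strain. Biotinylated cRNA was made from 0.3 µg of total RNA with a 3' IVT kit, per the labels' protocols.

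The authors deposited 1 intensity value per probe set and array on a linear scale, and their processing notes name RMA, which corrects background, makes the distributions of the arrays equal and summarises the probes of each probe set. The version and settings of RMA are not given in the sources used here, and neither is the genome build behind the probe sets. The median intensity of the 5 arrays lay between 45.4 and 46.6, and between 43.7% and 44.0% of the 45101 probe sets reached an intensity of 64. In 59.7% of probe sets at least 2 arrays held exactly the same value, and 643 probe sets were identical in all 5 arrays. Such ties occur when probe values are summarised by medians over few arrays, and they set many small differences to exactly 0. Detection calls were not used here.

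The intensities were converted to log2. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and only probe sets with 1 symbol were used. These stood for 18194 genes, of which 9012 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over the 5 arrays, and a gene was counted when its highest array reached log2 6, an intensity of 64, which left 11500 genes. Folds against an intensity below 64 rest on a value near background and are poorly determined.

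With 1 array per group no difference between strains has a replicate check, and p-values are given only for a contrast of both knockouts with wild type that takes strains as replicates. That contrast was fitted with limma, once over all 5 arrays and once over the 4 arrays of the lines with the line as a block, and was added after the data were seen. The RNA was pooled, so the spread between animals is also out of reach, and the number of arrays limits the precision. A gene was called higher or lower when the arrays differed by at least 2-fold, and 1.5-fold was used for members of lists and for chromosome neighbours. Each knockout was compared with the wild-type line of its own name, each wild-type line with C57, and the knockout comparisons with each other. The filter in the series' design text was applied as genes within 1.2-fold in C57 and 4D(+/+) and at least 1.5-fold away from C57, the same way, in the other 3 arrays.

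The median log2 difference of 42 gene lists was computed, 15 of pathways and checks and 27 of cell types and tissues, including tissues next to the lung. Of 547 listed symbols 500 were measured. The median of a list of at least 3 genes over the floor was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Members of a functional list vary together and random genes do not, so the percentile describes these arrays only. Between 15 and 21 of 38 lists lay outside the 2.5 to 97.5 percentile range in each of 6 comparisons, where 1.9 would be so by chance for unrelated genes. The neighbours of each targeted gene were the 100 genes over the floor on each side in the gene order of the RefSeq table for assembly GRCm38.p6, and their count was set against windows of the same shape elsewhere. That table was used for names and neighbour order, and no coordinates are given because the arrays name no build. It placed 11480 of the 11500 genes.

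Genes named were, for each knockout comparison, the 10 largest differences each way among those past 2-fold, and up to 4 members of each list with the largest absolute difference. For the wild-type lines the 5 largest each way were named, for genes shared by both knockouts the 10 with the largest smaller difference, for the filter all genes, and for neighbours the 5 largest. Genes named outside this rule are said to be so. The comparisons, lists, thresholds, naming rule and most alternatives were fixed before the data were examined. The alternatives were other fold thresholds, other floors, the median of a gene's probe sets, cyclic loess between arrays, centring on the median, other references and other window sizes. References that leave out a line's own wild type, and the count of neighbours set apart from each of the other 4 arrays, were added after the data were seen.

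The counting step was tested on simulated data for the comparison of 4D(-/-) with 4D(+/+) over 11500 genes, with 200 genes changed in each of 20 simulations. It recovered every gene changed by 2 log2 units and 99.7% of those changed by 1.5 log2 units, and called 0 unchanged genes. The noise in that simulation had a median SD of 0.12 on the log2 scale, estimated from the arrays themselves and not from replicates. At that noise unchanged genes hardly reach 2-fold, so the 0 sets no rate of false calls for the real arrays. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.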

Results

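Whole-lung expression profiles of 5 mouse strains were available, with 1 array of pooled RNA per strain. C57 served as the parental strain, and 4B(+/+), 4B(-/-), 4D(+/+) and 4D(-/-) were wild-type and knockout lines for the cyclic AMP phosphodiesterases PDE4B and PDE4D. Of 18194 measured genes 11500 reached the expression floor in at least 1 array. Across these genes the log2 values of 2 arrays correlated with Pearson coefficients between 0.976 and 0.991, over genes that are not independent replicates. The 3' to 5' ratio of the actin control probe sets lay between 1.62 and 1.88, and that of Gapdh between 1.31 and 1.77, the lowest in 4D(+/+) and the highest in 4D(-/-). Within the PDE4D comparison the Gapdh sign of RNA quality thus differed, but the actin ratio was 1.83 in 4D(+/+) and 1.86 in 4D(-/-). The Gapdh 3' signal itself was 3981 in 4D(+/+) and 2678 to 2978 in the other arrays. The B1 repeat control was brighter in 4B(-/-), at 2238, and in 4D(+/+), at 2044, than in the other 3 arrays, at 1363 to 1541.

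The targeted genes were still detected in their knockouts. The brightest of 3 Pde4b probe sets over the floor read 457 in 4B(-/-) against 558 in 4B(+/+), 1.22-fold lower, and the 3 wild-type arrays ranged from 438 to 558. Another Pde4b probe set read 397 in 4B(-/-) and 461 to 490 in the other 4 arrays, and the last read 164 against 199 to 258, so both were lowest in 4B(-/-). The only Pde4d probe set over the floor read 386 in 4D(-/-) and 523 in 4D(+/+), 1.35-fold lower, with the other wild-type arrays at 456 and 484. The position of the deleted parts is not given in the sources used here, and probes outside a deletion check nothing, so these values neither settle nor contradict the labels. Of 12 phosphodiesterases over the floor, 0 differed by 1.5-fold in either knockout comparison. Pde9a (1.25-fold higher) in 4B(-/-) and Pde6d (1.26-fold lower) in 4D(-/-) differed by the most apart from the targets.

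The first question was how the lung without PDE4B differed from its own wild-type line. In 4B(-/-), 12 genes were higher and 35 lower than in 4B(+/+) by at least 2-fold. Dntt, the terminal transferase of lymphocyte precursors, was 3.26-fold higher, the recombinase gene Rag1 2.62-fold, the thymus chemokine Ccl25 2.92-fold, its receptor Ccr9 2.41-fold, Sh2d1a 2.77-fold and the T-cell receptor segment Trbv1 2.26-fold. The largest rise was in the only probe set over the floor for Hprt, a purine salvage enzyme on the X chromosome, at 5841 against 1410 to 1844 in the other arrays, 3.84-fold above 4B(+/+). Whether that signal comes from the gene at its own place was not tested. The ventricular myosin light chain Myl2 (3.35-fold), the retinoic acid hydroxylase Cyp26b1 (2.58-fold) and Efcab7 (2.63-fold) were also higher.

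Falls in 4B(-/-) were larger than rises. The gastric lipase Lipf was 40.7-fold lower, at 234 against 9517, Dmbt1 24.1-fold, chromogranin A (Chga) 16.1-fold, parathyroid hormone (Pth) 11.6-fold and thyroglobulin (Tg) 10.7-fold. Wfdc18 was 8.08-fold lower, Dcpp3 7.56-fold, the skeletal myosin Myh4 6.81-fold, Slc26a7 6.15-fold and Scg2 5.89-fold. The 3 wild-type arrays themselves spanned 5390 to 13730 for Lipf and 3065 to 7717 for Tg. In 4B(+/+) the skeletal muscle, adipose and cartilage medians stood above C57, at 1.06, 1.72 and 1.62. However, Lipf, Dmbt1, Chga, Pth, Tg, Wfdc18, Dcpp3 and Myh4 were below every other array in 4B(-/-), by 3.47-fold (Myh4) to 21.6-fold (Lipf). C57 was among those arrays, so a surplus of tissue in the 4B(+/+) pool alone would not put these genes there. Whether differing amounts of tissue from beside the lung, in the 4B(-/-) pool or the others, account for the falls was not tested.

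Among the fixed lists, 3 of 5 T-cell genes were higher in 4B(-/-) and 0 lower, with a median log2 difference of 0.62. Cd8a was 2.04-fold, Cd3d 1.79-fold and Cd3g 1.54-fold higher, and both thymus genes over the floor, Dntt and Rag1, were among the rises above. Cd8a read 51.0 to 59.2 in the other 4 arrays, below the floor. The thymus median, over 2 genes, stood 4.15 above C57 in 4B(-/-) and 2.60 in 4B(+/+). Thymus tissue in the pool was not told apart from T cells of the lung. Of 16 cell cycle genes 3 were higher and 0 lower, with Ube2c 1.87-fold, Birc5 1.61-fold and Ccnb2 1.60-fold higher and a list median of 0.25. Of 18 immediate early genes, many of them targets of the cAMP-responsive factor CREB, 4 were lower and 0 higher, with a median of -0.29. Egr2 was 1.88-fold, Nr4a1 1.83-fold and Atf3 1.61-fold lower. Markers of other tissues moved as well. Of 9 skeletal muscle genes 8 were lower and 1 higher (median -0.93), of 8 cartilage genes 3 were lower (-0.52), of 6 adipose genes 2 were lower (-0.21), and of 10 cardiac muscle genes 1, Sln, was higher (0.43). The single thyroid gene over the floor was Tg.

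The remaining lists held few members past 1.5-fold in 4B(-/-). The chemokine Cxcl5 was 3.05-fold lower, the only one of 17 cytokine and chemokine genes past 1.5-fold. In the heat shock and stress list 1 of 20 genes was higher, Fkbp5 at 1.62-fold, and 2 were lower, Hspa1b at 1.92-fold and Hspa1a at 1.86-fold. Of 26 genes of cAMP production and sensing 1 was lower, Prkar2b at 1.65-fold, and of 4 neutrophil genes 1 was lower, Ltf at 1.98-fold. Every member lay within 1.5-fold in the lists of elastin proteases and inhibitors, elastic fibre and collagen, interferon response, xenobiotic metabolism, oxidative stress defence, circadian clock, and lipid and surfactant metabolism. The same held for the sex-chromosome check genes and for genes known to differ between C57BL/6J and other strains. Among the cell lists it held for alveolar type 1 and type 2, club, ciliated, endothelial and lymphatic endothelial cells. It held too for fibroblasts, smooth muscle, alveolar macrophages, monocytes and interstitial macrophages, dendritic, B, plasma, NK, mast, erythroid, platelet, mesothelial and squamous cells. Medians among these ranged from -0.30 for NK cells to 0.21 for mesothelium. Alveolar macrophage genes had a median of -0.22 and B-cell genes of -0.18, each with all members within 1.5-fold.

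In this comparison the medians of the T-cell, cell cycle and cardiac lists lay at the top end of the 10000 random lists, and those of the immediate early, skeletal muscle and cartilage lists at the bottom end. The counts depended on the reference, since against C57 in place of 4B(+/+) 79 genes were higher and 75 lower. The skeletal muscle, cartilage and adipose medians of 4B(-/-) were above C57, at 0.14, 0.97 and 0.87. With the mean of the 3 wild-type arrays as reference the medians of the adipose and cartilage lists turned to 0.04 and 0.21, and Cxcl5 stood 0.78 above it on the log2 scale, while T-cell genes had 0.79 and immediate early genes -0.50.

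**Figure D1:**
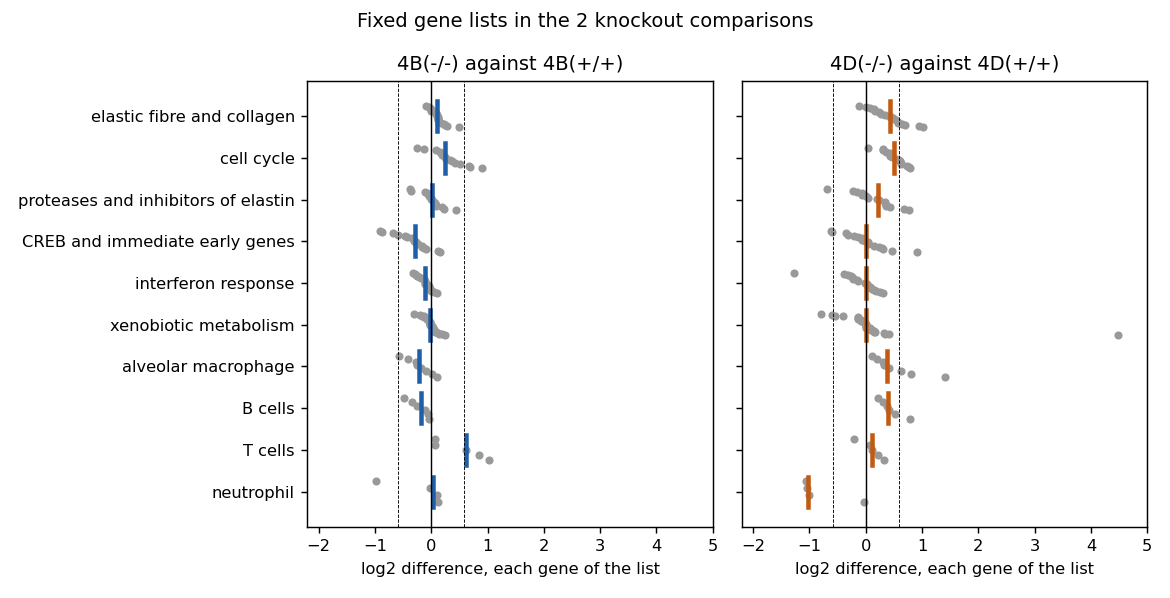
Log2 differences of single genes (grey points) and list medians (coloured bars) for 10 fixed lists in 4B(-/-) against 4B(+/+), left, and 4D(-/-) against 4D(+/+), right, with 1 pooled array per strain and dashed lines at 1.5-fold. The T-cell median is 0.62 on the left, the elastic fibre and collagen median 0.42 and the cell cycle median 0.50 on the right, and the lone point at 4.47 is Cyp1a1.

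The same question for PDE4D gave 24 genes higher and 174 lower in 4D(-/-) than in 4D(+/+). The largest rise was Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, at 1074 against 38.5 to 51.4 in the other 4 arrays, 22.2-fold above 4D(+/+). Glycam1, a mucin of high endothelial venules, was 13.1-fold higher, at 1116 against 85.2, though C57 read 588. Also higher were Adamts15 (2.89-fold), the immunoglobulin gene Ighg3 (2.86-fold), type II collagen Col2a1 (2.81-fold), Zbtb16 (2.74-fold) and the macrophage scavenger receptor Marco (2.66-fold). Col2a1 read 98.3 in 4D(-/-) against 35.0 in 4D(+/+), a value under the floor, and 142 in 4B(+/+). Alas2 of haem synthesis was 2.49-fold, Csf2rb2 2.39-fold and the glucocorticoid-responsive Fkbp5 2.38-fold higher.

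Of the 10 largest falls in 4D(-/-), Ucp1, the uncoupling protein of brown fat, was 10.7-fold lower and Cidea 7.64-fold. The muscle genes Mylpf, Tmod4, Pvalb and Tnni2 were 7.35-fold, 7.10-fold, 6.95-fold and 6.57-fold lower. Prpmp5 was 10.6-fold, Slc26a7 6.63-fold and Tnmd 6.22-fold lower, and Rag1 was 9.25-fold lower, with 10.6 in 4D(-/-) and 6.57 in C57, both below the floor. All 9 skeletal muscle genes and all 6 adipose genes over the floor were lower, with median folds of 4.84 and 3.99. Of 4 squamous and basal epithelial genes 3 were lower (median -0.64), among them Krt13 at 2.29-fold, and of 4 neutrophil genes 3 were lower (-1.03), with Ltf 2.10-fold, S100a8 2.07-fold and S100a9 2.01-fold. Tg was 4.58-fold lower.

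Of 21 genes of elastic fibre and collagen, 4 were higher in 4D(-/-) and 0 lower, with a median of 0.42. Col1a1 was 2.03-fold, elastin (Eln) 1.92-fold, fibronectin (Fn1) 1.61-fold and Col4a1 1.56-fold higher. Eln read 754 against 393 to 439 in the 3 wild-type arrays and 616 in 4B(-/-). Of 16 cell cycle genes 7 were higher and 0 lower, with a median of 0.50, led by Mki67 (1.72-fold), Prc1 (1.70-fold), Ube2c (1.67-fold) and Nusap1 (1.55-fold). Of 8 alveolar macrophage genes 3 were higher and 0 lower (0.37), namely Marco, Fabp1 at 1.74-fold and Chil3 at 1.55-fold. Of 16 proteases and inhibitors of elastin 2 were higher, Serpina3n at 1.71-fold and Mmp2 at 1.60-fold, and 1 was lower, Timp4 (median 0.22). Of 6 B-cell genes 1 was higher, H2-Ob at 1.72-fold (0.40), and both erythroid genes over the floor were higher, Alas2 and Hbb-b2, the latter at 2.10-fold.

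Of 17 cytokine and chemokine genes 2 were higher, Ccl5 at 2.14-fold and Il33 at 1.67-fold, and 2 lower, Cxcl5 at 2.42-fold and Ccl20. In heat shock and stress 3 of 20 were higher, Fkbp5, Cdkn1a at 1.87-fold and Tsc22d3 at 1.59-fold, and 1 was lower, Hspe1 at 1.87-fold. Of 20 interferon genes 1 was lower, Ifi27l2a at 2.41-fold, of 20 lipid and surfactant genes 1 was lower, Elovl6 at 2.89-fold, and of 31 xenobiotic genes 1 was higher, Cyp1a1, and 2 lower. Of 18 immediate early genes 1 was higher, Nr4a3, and 2 lower, Ccn1 and Atf3, around a median of 0.01. Of 26 genes of cAMP production and sensing 1 was higher, Ptger4, and 1 lower, Prkar2b at 1.54-fold. Nnt was the 1 gene of 19 in oxidative stress defence past 1.5-fold, and also of 3 known strain-variable genes. Of 8 club cell genes 2 were lower, of 8 cartilage genes 2 higher, of 4 mesothelial genes 1 lower, Msln at 2.25-fold, of 10 cardiac genes 1 lower, Sln at 1.91-fold, and of 2 thymus genes 1 lower, Rag1. Every member lay within 1.5-fold for the circadian clock, the sex-chromosome check genes, alveolar type 1 (median 0.23) and type 2 (0.19), ciliated (-0.30), endothelial, lymphatic, fibroblast and smooth muscle (-0.30) lists. This was also so for monocytes, dendritic (0.40), T, plasma (0.23), NK, mast and platelet (-0.39) lists.

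The elastic fibre, cell cycle, alveolar macrophage and B-cell medians lay at the top end of the random lists, and the skeletal muscle, adipose and neutrophil medians at the bottom end. The counts depended on the wild-type array, because with C57 as reference 39 genes were higher and 23 lower, and with the mean of C57 and 4B(+/+) 15 and 16. Against C57 the 4D(-/-) medians were 0.35 for elastic fibre, 0.51 for cell cycle, 0.29 for alveolar macrophage and -0.32 for adipose genes, but -0.26 for B-cell, 0.94 for skeletal muscle and -0.04 for neutrophil genes. Against the mean of the 3 wild-type arrays the elastic fibre median was 0.37, the cell cycle median 0.56 and the alveolar macrophage median 0.28, whereas the squamous median turned to 0.58 and Krt13 to 1.35.

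**Figure D2:**
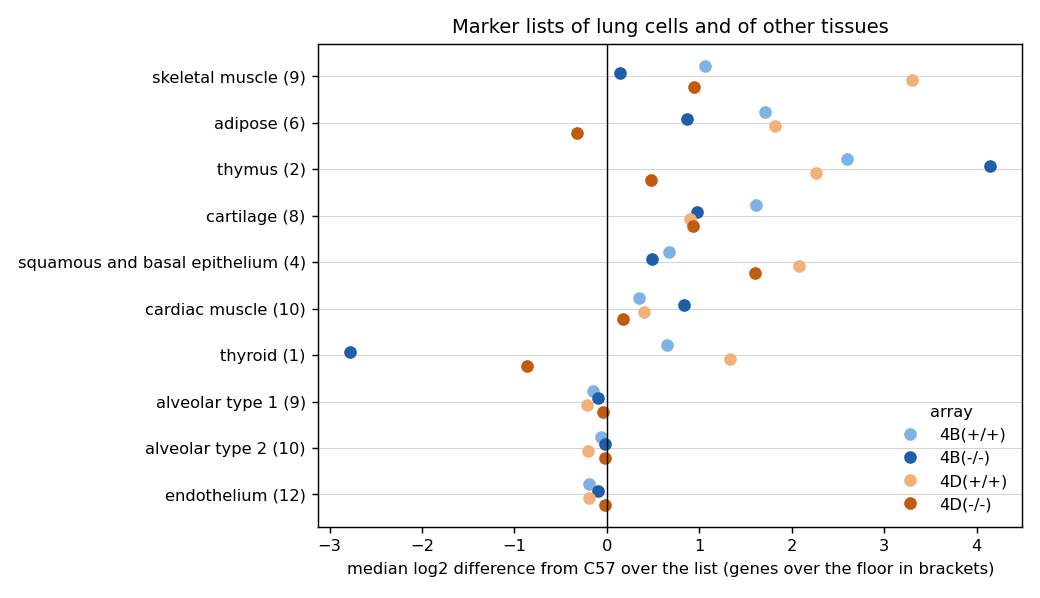
Median log2 difference from C57 of 10 marker lists (rows, number of genes over the floor in brackets) in each of the other 4 arrays (coloured points, 1 pooled array each). Skeletal muscle stands at 3.30 in 4D(+/+) and cartilage at 1.62 in 4B(+/+), while the alveolar type 1 and type 2 and endothelial lists lie between -0.21 and -0.02 in every array.

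The wild-type lines were compared with C57 to see what the backcrossed lines carried before any knockout. In 4B(+/+), 96 genes were higher and 24 lower than in C57. The largest rise was the neutrophil chemokine Cxcl5 (31.7-fold, from 18.7), followed by Rag1 (19.2-fold, from 6.57), Cnmd (7.23-fold), Col10a1 (5.67-fold) and Comp (5.23-fold), the last 3 being cartilage genes. The largest falls were the clock output gene Dbp (14.1-fold), Glycam1 (6.75-fold) and the immediate early genes Egr3 (4.47-fold), Egr1 (3.82-fold) and Nr4a1 (3.74-fold). In 4D(+/+), 210 genes were higher and 21 lower, led by the keratin Krt13 (119 against 7.45), Rag1 (14.9-fold), Mylpf (14.7-fold), Tnni2 (12.6-fold) and Pvalb (11.4-fold). Dbp (10.6-fold), Glycam1 (6.91-fold), Per3 (3.45-fold), Hlf (3.28-fold) and Egr1 (3.10-fold) fell most.

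Several lists of tissues other than lung were compared between the wild-type lines and C57. All 9 skeletal muscle genes were higher in each, with medians of 1.06 in 4B(+/+) and 3.30 in 4D(+/+). Of 6 adipose genes 6 and 5 were higher (1.72 and 1.82), of 8 cartilage genes 8 and 5 (1.62 and 0.90), and of 4 squamous genes 2 and 4 (0.67 and 2.08). Of 10 cardiac muscle genes 1 and 2 were higher (0.35 and 0.41). Among immune genes, 5 of 6 B-cell genes were lower in each line (-0.68 and -0.66) and 3 of 4 neutrophil genes higher (0.59 and 0.93). Pde3b was 1.71-fold higher in 4B(+/+) than in C57, and 0 phosphodiesterases passed 1.5-fold in 4D(+/+).

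The circadian clock list separated C57 from the other strains. Of 16 clock genes over the floor 10 were lower and 3 higher in 4B(+/+), and 9 lower and 3 higher in 4D(+/+), with medians of -0.72 in both. Dbp read 2475 in C57 and between 146 and 247 in the other 4 arrays, while the core activators Arntl and Npas2, named after their values were seen, were 2.52-fold and 2.55-fold higher in 4B(+/+). Immediate early genes were lower, 8 of 18 in 4B(+/+) and 7 in 4D(+/+), with 1 higher in each (-0.46 and -0.39). Heat shock and stress genes were higher, 7 and 8 of 20 with 0 lower (0.44 and 0.40), led by Hsph1.

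In total 65 genes were higher and 15 lower than C57 in both wild-type lines. Independent lists would share 1.75 and 0.044 genes, and 100 simulations of unchanged arrays gave at most 0. The simulated noise had a median SD of 0.12 per array, and the log2 differences of the 2 real comparisons had SDs of 0.28 and 0.36. Unchanged genes could thus hardly reach 2-fold in the simulations, so their 0 is no check on this excess. Both comparisons use the same C57 array, which could not be split, so part of the excess may come from it. In all 4 other strains 12 genes were higher and 13 lower than in C57. Of these, chosen for naming after their values were seen, the immunoglobulin genes Igha and Jchain were at least 2.33-fold and 2.02-fold higher, and the macrophage elastase Mmp12 at least 2.06-fold lower.

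**Figure D3:**
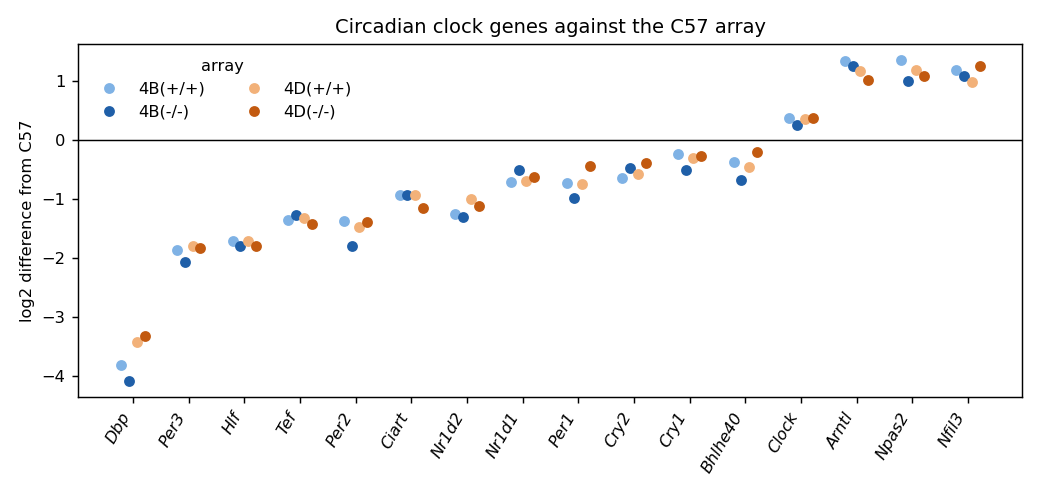
Log2 difference from C57 of the 16 circadian clock genes over the floor, ordered by their value in 4D(-/-), with 1 point per array. Dbp lies between -4.08 and -3.33 and Per3 between -2.06 and -1.79 in the other 4 arrays.

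The knockouts were then compared with each other for shared differences. Genes past 2-fold in both against their own wild types numbered 26, all lower, against 0.53 for independent lists, and 0 were higher in both. The number depends on the reference, since 4 genes, Prpmp5, Scg2, Slc26a7 and Tg, lay at least 1.5-fold under all 3 wild-type arrays in both knockouts, while Pth and Chga in 4D(-/-) and Ucp1 in 4B(-/-) were above C57. Slc26a7, Scg2, Tg, Prpmp5 and Pth had the largest smaller fall, followed by Tnmd, Tff2, Chga, Ucp1 and Actn3. Tg was 10.7-fold lower in 4B(-/-) and 4.58-fold in 4D(-/-), and Tff2 4.38-fold and 3.21-fold. Tg and Pth are products of the thyroid and parathyroid, Ucp1 of brown fat and Actn3 of fast skeletal muscle. Whether differing amounts of such tissue in the pools account for the shared falls was not tested. Opposite moves were seen in 4 genes, 3 of them higher in 4B(-/-) and 1 higher in 4D(-/-). Across all genes the 2 knockout differences had a Pearson coefficient of 0.06 and a Spearman coefficient of -0.23, over genes that are not independent.

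The design text of the series names a filter for genes at the C57 level in 4D(+/+) and at another level in 4B(+/+), 4B(-/-) and 4D(-/-). It left 3 genes, all higher in those 3 arrays. The cartilage collagens Col2a1 (1.87-fold to 3.38-fold above C57) and Col9a1 (1.70-fold to 3.06-fold) passed, as did Tmem252 (1.52-fold to 2.08-fold). In C57 and 4D(+/+), Col2a1 read 42.0 and 35.0 and Col9a1 38.9 and 40.2, all below the floor. Their equal level in those arrays thus rests on values near background. Tmem267, named after its values were seen, passed without the demand for 1 direction, since it was higher in both 4B arrays and 2.68-fold lower in 4D(-/-). When each other pair of arrays was put in the place of C57 and 4D(+/+), 0 to 42 genes passed, with a median of 4.0, and 6 of all 10 pairs gave at least 3. Simulated unchanged arrays gave at most 1 gene in 100 simulations. Their noise was smaller than the spread between the real arrays, so this is no check on the 3 genes.

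The chromosomes around the targeted genes were examined because backcrossed knockout lines can keep donor DNA there. Of 200 neighbours of Pde4b on chromosome 4, 3 differed by 1.5-fold between 4B(-/-) and 4B(+/+), namely Efcab7 (2.63-fold higher), Dio1 (2.16-fold lower) and Hyi (1.93-fold higher), at percentile 61.5 of windows of that size. Around Pde4d on chromosome 13 there were 100 genes before and 32 after it, and 16 of the 132 differed between 4D(-/-) and 4D(+/+). That was at percentile 99.7, and 49 of 8839 overlapping windows, the one around Pde4d among them, held as many. The same neighbours also differed often where Pde4d was not the targeted gene, with 15 between 4B(-/-) and C57 at percentile 98.0, and 13 between 4D(+/+) and C57 at percentile 98.9. The largest differences were Hspb3 (3.30-fold lower), Tmem267 (3.01-fold lower), Cmya5 (2.78-fold lower), Ckmt2 (2.45-fold lower) and Isl1 (2.18-fold lower). Hspb3, Cmya5 and Ckmt2 are muscle genes, and the skeletal muscle list was lower in the same comparison. Between 4D(-/-) and C57, 12 neighbours differed, with 3 of 8839 overlapping windows, the one around Pde4d among them, holding as many.

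Neighbours of Pde4d that stood at least 1.5-fold from each of the other 4 arrays were also counted, a count added after the data were seen. There were 5 in 4D(-/-), namely Tmem267, Nnt, 4833420G17Rik, Arsk and Elovl7. Nnt, the nicotinamide nucleotide transhydrogenase of mitochondria, read 1212 in 4D(-/-) and 345 to 569 in the other arrays, and Tmem267 read 29.6 against 79.4 to 124.

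**Figure D4:**
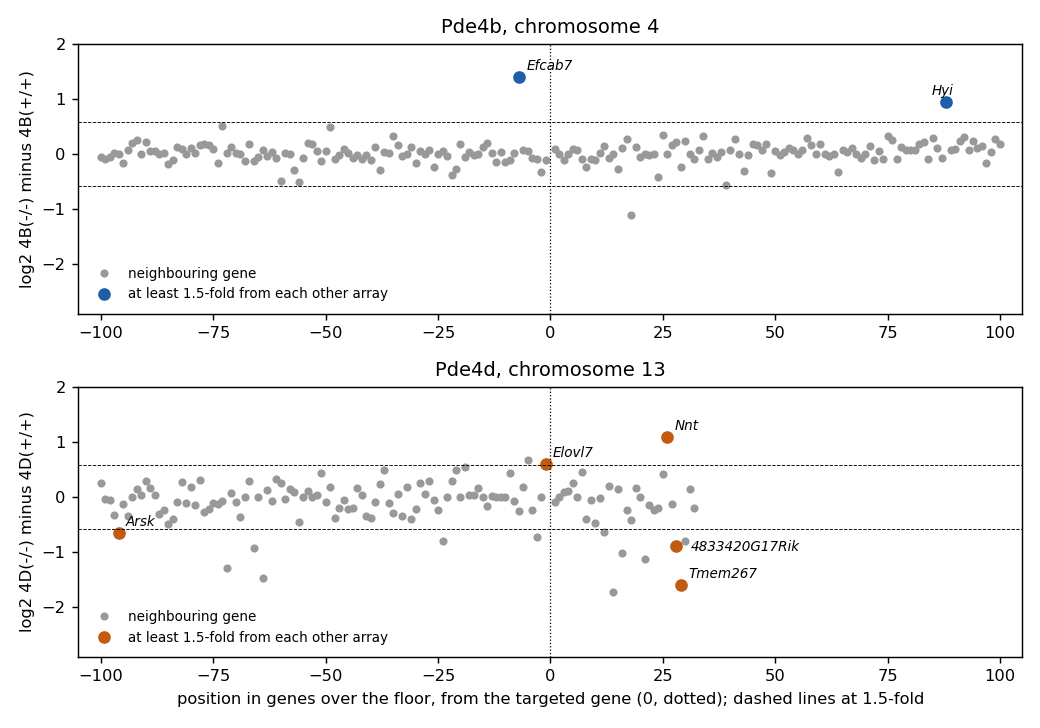
Log2 difference of each gene over the floor by its order along the chromosome from Pde4b (upper panel, 4B(-/-) minus 4B(+/+)) and Pde4d (lower panel, 4D(-/-) minus 4D(+/+)), with dashed lines at 1.5-fold. Coloured points are genes of the knockout array at least 1.5-fold from each of the other 4 arrays, 2 around Pde4b and 5 around Pde4d, and the lower panel ends 32 genes after Pde4d at the chromosome end.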

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

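All explanations weighed in this part were tested after the results they concern had been seen. The count of genes beside Pde4d against other windows was planned, and its restriction to genes set apart from every other array was not. Genes named in this weighing were chosen after their values were seen.

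The first pattern was the set of 174 genes lower in 4D(-/-) than in 4D(+/+). Of these, 98.3% were at least 1.5-fold higher in 4D(+/+) than in C57, and their median in 4D(-/-) lay 0.18 above C57 on the log2 scale, so loss of Pde4d lowering them as a set is argued against, since 4.598% lay at least 1.5-fold under each wild-type array. Tissue from beside the lung in the 4D(+/+) pool may account for part of the set. The skeletal muscle genes Tnnc2 and Mylpf read 9432 and 4979 in that array against 902 and 338 in C57. Of the 40 genes over the floor on lists of such tissue 16 are in the set, which holds 174 of 11500 genes. They include 8 of 9 skeletal muscle and 5 of 6 adipose genes, but 0 of 8 cartilage and 0 of 10 cardiac muscle genes. Most of the set is on none of these lists, so how much of it tissue accounts for is not shown. The 98.3% rests on the same 4D(+/+) array as the pattern, 121 of the 174 genes were at least 1.5-fold higher there than in both C57 and 4B(+/+), neither value shows by itself that tissue made them so, and a real difference of the 4D(+/+) animals stays open and untested. The 8 genes under every wild-type array, Pck1, Prpmp5, Scg2, Slc26a7, Slc5a8, Tg, Tmem267 and Ucp1, stay open, as there is 1 array of 4D(-/-). Tg and Ucp1 are on the thyroid and adipose lists, and Tg read 3065 to 7717 in the wild-type arrays. Varying tissue in the pools thus stays among the open explanations for both. It stays open for Slc26a7 and Scg2 too, which ranked the 5 arrays in the same order as Tg. Scg2 was below the floor in C57 and both knockouts. For Pck1, Prpmp5 and Slc5a8 varying tissue was not tested. Tmem267 lies beside Pde4d and is part of the third pattern below.

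The second pattern was the circadian clock list, apart in C57 from the other 4 arrays. Clock genes were divided for this test into 11 grouped with Dbp and 5 opposed to them, after the values were seen, and the smallest median of the opposed arm against C57 was 0.98 while the other arm had medians of -1.28 to -0.997. A different time of day at collection of the C57 lungs may account for this, although Cry1 of the opposed arm was lower and not higher. A scaling of the C57 array shared by genes of like expression is argued against. The clock list median lay at least 12.1 SDs out among random lists matched on expression, and the arms moved in opposite directions. These are the same medians that set the list apart, so they are no independent test. RMA had already made the distributions of the arrays equal, so a uniform scaling could not have shown here. Background of the 4 backcrossed lines cannot be told apart from time of day with 1 C57 array.

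The third pattern was the 5 genes beside Pde4d that stood at least 1.5-fold from every other array in 4D(-/-). Donor DNA kept beside the targeted gene may account for them, since the count was at percentile 99.98 of windows of its size. Those windows overlap and include the one around Pde4d itself. Among the 5 is Nnt, of which C57BL/6J is known to carry a defective copy. Its place as highest in 4D(-/-) follows from the rule that chose the genes and is no further sign of donor DNA. A stretch of genes that differs in other arrays too stays open. By the planned count the same window held 15 genes differing between 4B(-/-) and C57, at percentile 98.0. Of genes set apart there, C57 had 3 at percentile 95.7, although 4B(+/+) had 0 and 4B(-/-) 1, at percentiles 45.5 and 69.3. In 4D(+/+) there were 4, Ckmt2, Cmya5, Hspb3 and Isl1, at percentile 91.3. Ckmt2, Cmya5 and Hspb3 are muscle genes, and the skeletal muscle median stood 3.30 above C57 in 4D(+/+). These genes may thus reflect muscle in that pool and not the stretch, which was not tested. Sequence variants under the probes also stay open, with 2 genes, Nnt and 4833420G17Rik, having a second probe set past 1.5-fold the same way Arsk and Elovl7 having other probe sets of which 0 did so, and Tmem267 having no other probe set over the floor.

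The remaining results are given because the effects in the 2 knockout lines went opposite ways, and the differences between the lines were not tested. On the log2 scale Ccl25 stood 1.55 above its wild type in 4B(-/-) and at -1.54 in 4D(-/-), Myl2 at 1.75 and -1.54, and Rag1 at 1.39 and -3.21, with 4D(-/-) below the floor. Glycam1 stood at -2.41 in 4B(-/-), where it read 16.4 and was below the floor, and at 3.71 in 4D(-/-). Of the lists, ciliated genes had medians of 0.16 and -0.30, alveolar macrophage genes -0.22 and 0.37, B-cell genes -0.18 and 0.40, plasma cell genes -0.14 and 0.23, and cardiac muscle genes 0.43 and -0.20. The opposition depends on the reference, since against C57 both knockouts went the same way for B-cell genes (-0.85 and -0.26), plasma cell genes (0.08 and 0.14) and cardiac muscle genes (0.83 and 0.17), and with the mean of the 3 wild-type arrays the plasma cell median of 4B(-/-) became 0.0664. Rag1 was likewise above C57 in both knockouts, though C57, at 6.57, and 4D(-/-) were below the floor.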

How the results depend on the processing

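Alternatives named below that leave out a line's own wild type, and the count of neighbours apart from every other array, were added after the data were seen. Counts stayed within 1.5 times their value in all 12 recomputed with cyclic loess, all 8 with centring on the median, all 14 with no floor, and both counts of neighbours with 50 or 200 genes on each side. RMA had already made the distributions of the arrays equal, which leaves little for centring or cyclic loess to change. Among list medians and named genes, 424 moved by less than their spread (the SD of random medians for a list, of all genes for a gene) under cyclic loess and 1 by more. With the mean of the 3 wild-type arrays as reference 279 moved by less, 138 by more and 8 changed direction, with the median of a gene's probe sets 358 by less and 61 by more, and with no floor 67 by less and 9 by more. At 1.5-fold the counts higher and lower were 44 and 107 in 4B(-/-) against 4B(+/+), 126 and 521 in 4D(-/-) against 4D(+/+), 256 and 153 in 4B(+/+) against C57, and 489 and 143 in 4D(+/+) against C57, and the genes shared by both knockouts 75. At 3-fold they were 3 and 23, 2 and 68, 26 and 8, and 97 and 5. With the floor at log2 8 the higher counts were 5, 13, 56 and 118, and the lower count of 4D(-/-) was 98, because fewer genes were counted. With the median of a gene's probe sets, 15 genes were higher in 4D(-/-), 15 lower in 4B(+/+) and 13 lower in 4D(+/+). With C57 as reference the counts were 79 higher and 75 lower in 4B(-/-), and 39 and 23 in 4D(-/-). With the mean of the 3 wild-type arrays, 56 were lower in 4B(-/-), and 11 higher and 27 lower in 4D(-/-). Without 4B(+/+), 26 were higher and 67 lower in 4B(-/-), and without 4D(+/+), 15 higher and 16 lower in 4D(-/-). The filter gave 0 genes when at least 2-fold was asked, 10 with level taken as within 1.5-fold, and 1 with the floor at log2 8. Of the neighbours of Pde4d, 7 differed at 2-fold and 5 stood apart from each other array. The mean of the 3 wild-type arrays also turned the direction of some results. In 4B(-/-) the list medians became 0.0097 for interferon response, 0.0555 for heat shock and stress, 0.0664 for plasma cells, 0.043 for adipose and 0.21 for cartilage, and Cxcl5 stood at 0.78. In 4D(-/-) the squamous list became 0.58 and Krt13 1.35. The causes were not tested, beyond what a setting does by its own construction. Probe sets near an intensity of 64 limit what can be said of dim genes.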

Other observations

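All counts and genes in this part were chosen after the data were seen.

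Beyond the comparisons above, the arrays differed in how many genes stood apart from all the other 4. At 1.5-fold, 146 genes were higher and 5 lower in 4D(+/+) alone, 37 and 46 in C57, 22 and 39 in 4B(-/-), 21 and 11 in 4D(-/-), and 7 and 1 in 4B(+/+). In 4D(-/-), Chil4, a chitinase-like protein, was at least 2.37-fold above every other array, at 65.2. In 4B(-/-), the glycoprotein Gp2 was at least 3.03-fold below every other array. Compared with C57, the cartilage genes Cytl1 (765 in C57, 1916 to 3695 elsewhere) and Frzb (40.3 in C57, 101 to 146 elsewhere) were higher in all 4 other strains, and the tetraspanin Tspan4 (1316 in C57, 493 to 558 elsewhere) was lower.

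Of the 10 ways to set 2 arrays against the other 3, the pair of knockouts separated 5 genes by at least 1.5-fold, with Ube2c higher and Prpmp5, Scg2, Slc26a7 and Tg lower in both knockouts, although for Prpmp5 and Scg2 the knockouts and at least 1 wild-type array were below the floor. The other pairs separated 0 to 46 genes, the most being C57 with 4D(-/-), so the knockouts were not the pair with the most genes in common. Ube2c, a ubiquitin-conjugating enzyme of mitosis, read 108 and 107 in the knockouts and 57.6 to 67.6 in the wild types. A limma contrast of the 2 knockouts with the 3 wild types, two-sided and with strains as replicates, gave 0 of 11500 genes at an adjusted p under 0.05 and 177 at an unadjusted p under 0.05, where 575 would be so by chance. Over the 4 arrays of the lines with the line as a block, limma gave 0 genes and 208. The knockouts lack different genes, the fits have 3 and 1 residual degrees of freedom, and a low count does not show that the knockouts share no difference.

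Hprt stood out in 4B(-/-), and 0 of its 20 nearest neighbours over the floor on the X chromosome, 10 on each side, differed by 1.5-fold between 4B(-/-) and 4B(+/+), the largest being 1.46-fold. The source of the Hprt signal itself was not tested. Among 1569 probe sets over the floor without a gene symbol, 3 were higher and 4 lower in 4B(-/-) than in 4B(+/+), and 7 higher and 14 lower in 4D(-/-) than in 4D(+/+).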
